A study of Ovis aries with 12 samples.

How the data were processed

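Messenger RNA was sequenced from 12 libraries of 5-month-old Tan sheep (Ovis aries), 3 libraries for each of 4 diets. The diets were a basal diet, called the control here, and the basal diet with 0.5%, 1% or 2% succinate. The feeding trial held 36 sheep, 9 per diet. The sources used here do not say whether each library came from a separate sheep, so the p-values measure the spread between these samples. The labels name no tissue, and the series title concerns proliferation of rumen epithelial cells.

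According to the submitters' processing notes, total RNA was extracted with Trizol and libraries were made with a NEBNext Ultra II RNA kit; reads were trimmed with cutadapt 1.15, aligned with HISAT2 2.1.0 and counted with HTSeq 0.9.1. The deposited values are FPKM (fragments scaled to gene length and library total) made by the authors, for 21257 genes with their lengths and positions. Neither the genome build behind these positions nor the strand setting of the counting is given in the sources used here. FPKM times gene length was a whole number of reads, within 0.01 of a read, for 100% of the values, which gave the reads and the total per library. These totals are reads assigned to genes. A count of 0 reads allows up to 3 reads, which is 0.16 to 0.194 CPM (reads scaled to the library total) in these libraries; this floor covers counting error only.

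Gene IDs matched a RefSeq gene table (assembly ARS-UI_Ramb_v3.0) for 20874 genes, 98.2% of the file. The table was used only to replace 437 names made of LOC numbers by a symbol and to name chromosomes. The start and end of a gene were the same in the file and in the table for 41.5% of the genes, so positions printed here are those of the file.

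The unit of the values set the test. The plan, made before the data were examined, was a count model if the file held counts, and limma-trend if it held only FPKM; the second applied. Values were transformed as log2(FPKM + 1), with a pseudocount of 1. This shrinks the differences of genes near or below 1 FPKM. The sizes of log2 differences are therefore not comparable between scarce and abundant genes or lists. The 12095 genes with at least 1 FPKM in at least 3 libraries were tested. limma 3.58.1 (R 4.3.3, statmod 1.5.0) fitted the 4 diets over all 12 libraries together, with an intensity trend and robust moderation, and tested each dose against the control, each pair of doses, a linear slope on succinate percent, and any difference among the diets with an F test. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. With 3 libraries against 3, an exact test of a single value cannot go below 0.1, so none is given for such pairs.

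For 31 gene lists, also fixed before the data were examined, limma's camera compared each list with all other genes at a preset correlation of 0.01. The 26 lists with at least 5 tested members gave 78 tests over the 3 doses, adjusted together. The lists were G1 and G1/S regulators; S phase and mitosis; apoptosis; growth factor and PI3K-AKT signalling; the basal layer of the stratified epithelium; suprabasal differentiation; cell junctions; acid, proton and ion transport; succinate and the tricarboxylic acid cycle; oxidative phosphorylation; ketogenesis and short-chain fatty acid use; cholesterol synthesis; glycolysis; hypoxia-inducible factor targets; ribosomal proteins; inflammation; interferon response; WNT, NOTCH, TGF-beta and Hippo signalling; immediate early and heat shock genes; endoplasmic reticulum stress; and markers of 11 cell types (smooth muscle, fibroblasts, endothelium, T and natural killer cells, B and plasma cells, macrophages and dendritic cells, neutrophils and mast cells, red blood cells, neurons and glia, adipocytes, skeletal muscle). A list score is the mean over its tested members of log2(FPKM + 1) minus each member's mean over the 12 libraries. The camera test was repeated with a correlation estimated from these libraries. That estimate ran from 0.0155 for apoptosis to 0.8803 for ribosomal proteins. It was 0.632 for oxidative phosphorylation, 0.566 for S phase and mitosis and 0.5322 for macrophage and dendritic cell markers. Where members vary together by far more than the preset 0.01, the p at the preset is too small. The fry test asked whether a list's members move, on balance, in a single direction.

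Genes to be named were set by a rule fixed at the same time: up to 8 in each direction past the threshold, with a symbol, a mean log2 CPM of at least 1 and no overlap between the 2 diets. Fewer than 4 in a direction were filled to 4 by the smallest p, and up to 3 members past the threshold were taken from each list. A fixed set (including SUCNR1, SDHA, SDHB, SUCLG1, HIF1A, CCND1, CDK4, MKI67, PCNA, SLC16A1, SLC9A3, KRT5, KRT14, ACTA2) was named whatever its p. For the trend and the F test the rule took the 8 genes with the smallest p. List members given as examples beyond this rule were chosen after their values were seen, as was the comparison of all succinate diets with the control.

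The procedure was tested on simulated data with 21257 genes over 5 runs, with known changes at 1% succinate alone. It called 7.16% of genes changed 1.5-fold, 36.4% of those changed 2-fold and 76.4% of those changed 4-fold, with a mean of 6.4 false calls at that dose and 0 calls at the other doses. A raised list was called in 5 of 5 runs, and 0 of 394 other list tests passed. The simulated genes varied independently of each other, with no length trend between libraries. These list results therefore do not cover lists whose members vary together.

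The alternatives tried were quantile normalization, TMM scaling, a lower or no filter on FPKM, a pseudocount of 0.1, each library left out in turn, fits of the 6 libraries compared, a test beyond a 1.5-fold change (limma treat), dose rank for the trend, the replicate number as a block, limma-voom on the recovered reads, removal of a trend with gene length, library weights, and leaving out 2 libraries that stood apart. No file, library or column of values per sample was left out. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.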

Results

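Gene expression was measured by RNA sequencing in 12 libraries of Tan sheep, 3 from each of 4 diets with 0, 0.5%, 1% or 2% added succinate, a short dicarboxylic acid of the tricarboxylic acid cycle. The control libraries held 16426453, 16168238 and 16098638 reads assigned to genes. The 0.5% libraries held 16930987, 16706328 and 18229291, the 1% libraries 17477267, 15489883 and 16701613, and the 2% libraries 17128959, 18717309 and 15637779, each in the order of replicates 1 to 3. Between 15602 and 16222 genes had at least 1 read in a library. The 10 most abundant genes took 12.1% to 16.8% of the reads, and mitochondrial genes 2.9% to 6.64%.

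Pearson's r between libraries, across tested genes, ran from 0.9086 to 0.9807. Replicates 2 and 3 of the 1% diet stood apart: without them the lowest r was 0.9439. They had the highest values on the first principal component, 35.2 and 55, which held 31.6% of the variance. The gene loadings of this component had a Spearman correlation of 0.58 with gene length. In these 2 libraries long genes were higher relative to short genes, with Spearman correlations of 0.58 and 0.43 between a gene's deviation and its length. Replicate 2 of the 0.5% diet had the opposite trend, at -0.63, as did control replicates 1 and 2, at -0.31 and -0.37, which enter every comparison with the control. Replicate 2 of the 2% diet was at 0.28, and the other 6 libraries lay between -0.16 and 0.06. These are correlations across genes, which are not independent replicates. On the second component, which held 16.4% of the variance, replicate 1 of the 0.5% diet was highest, at 37.5. Its pair with control replicate 2 gave the r of 0.9439 above. No sequencing batch or date was given, and no batch could be tested. Each of the 66 pairs of libraries differed far beyond counting error, with a chi-square per gene of at least 21.8, so no library was a copy of another.

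Genes of contractile smooth muscle were among the most abundant. Over the 12 libraries, DES (desmin, a muscle intermediate filament) averaged 9930 ± 2680 FPKM (SD, n = 12), MYL9 (a myosin light chain) 7780 ± 1590, TAGLN (transgelin) 6210 ± 1530, ACTG2 (enteric smooth muscle actin) 5460 ± 1270 and CNN1 (calponin) 5090 ± 1420. All 15 smooth muscle markers were among the top 5% of genes, and 13 were in the top 1%. Lower levels were found for the fibroblast markers SPARC, at 938 FPKM, and DCN, at 480, and for the endothelial marker PECAM1, at 42.6.

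Epithelial markers were at or near 0. KRT5, a keratin of basal epithelial cells, had 0 reads in all 12 libraries, as did KRT4, KRT15, TP63 and IVL. KRT14 (LOC101118459 in the file), another basal keratin, averaged 0.0359 ± 0.0621 FPKM (SD, n = 3) at 1% and 0.0213 ± 0.037 at 2% succinate, and was 0 in the other diets. Of 36 suprabasal differentiation genes in the file, 4 were abundant enough to be tested: KLF4, PPL, SBSN and DSC2. The basal layer list had 10 tested members, led by CAV1 at 767, POSTN at 366 and ITGB1 at 306 FPKM, which other tissue cells also express. Blood cells were scarce, with HBB, a haemoglobin chain, at 1.52 FPKM and CD3E, a T cell receptor component, at 0.932 FPKM.

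**Figure D1:**
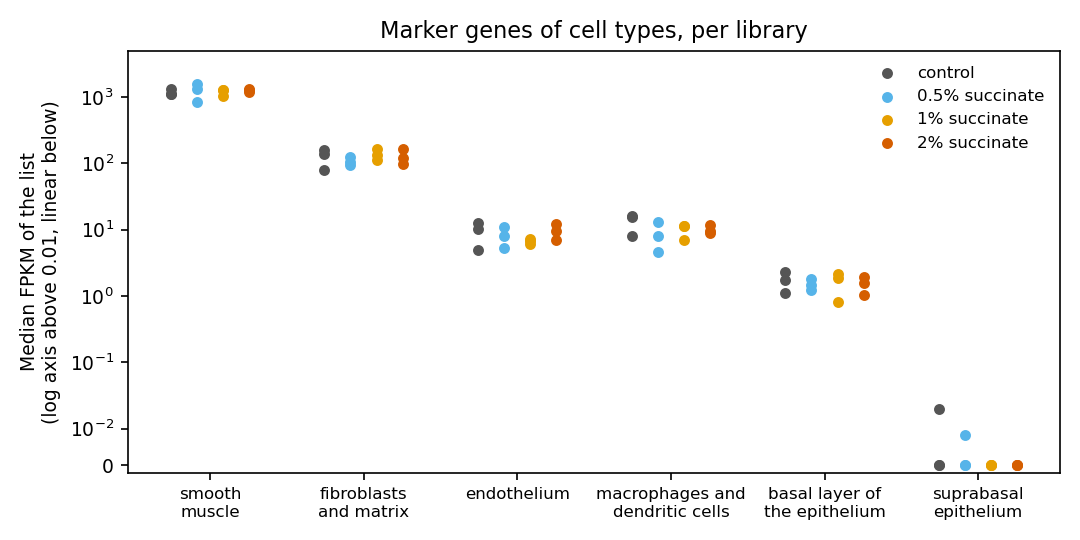
Median FPKM of the marker genes of 6 cell types in each of the 12 libraries (points, coloured by diet; logarithmic axis above 0.01 FPKM, linear below). Smooth muscle medians lay between 830 and 1580 FPKM, and suprabasal epithelium medians were 0.0199 FPKM or lower in every library.

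The comparison of each dose with the control asks what dietary succinate changed. At 0.5% succinate, LGALS1, which encodes the sugar-binding protein galectin-1, stood at 439 ± 195 FPKM against 164 ± 21 in the control (SD, n = 3 in each). HINT1, a nucleotide hydrolase, stood at 21.4 ± 6.67 against 82.2 ± 12.3. HAGHL was 8.49 ± 1.26 against 4.91 ± 0.683, FNDC10 12.9 ± 3.33 against 6.88 ± 0.184 and DHRSX 5.91 ± 0.115 against 3.45 ± 0.573. Lower values were found for ISM1, a secreted protein, at 1.55 ± 0.926 against 5.09 ± 1.79, for TYW5, an enzyme of transfer RNA modification, at 4.09 ± 0.994 against 8.11 ± 1.31, and for WHRN at 1.22 ± 0.157 against 3.63 ± 0.77. LGALS1 lies on chromosome 3 from 215343792 to 215347038; its log2 difference was 1.33 (SE 0.28), and that of HINT1, on chromosome 5, was -1.93 (SE 0.43). None of these 8 genes passed the limma test, at an adjusted p of 0.883 each.

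By limma, 0 of 12095 genes passed at 0.5% succinate; 562 had an unadjusted p under 0.05, 114 higher and 448 lower, and limma-voom gave 0 genes with 447. In 1467 genes, 12.1%, the 3 libraries of each diet did not overlap, where chance gives 10%. The median log2 difference of all genes was -0.11, and it became -0.01 with TMM scaling, so the differences at this dose are best read against that shift.

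Among the gene groups at 0.5% succinate, genes of S phase and mitosis, which are made in dividing cells, were higher in 28 of 32 tested members, with a median log2 difference of 0.49. CDC20, a mitotic regulator, was 2.07 ± 2.03 against 0.175 ± 0.153 FPKM and CCNB1, cyclin B1, 3.1 ± 2.09 against 0.712 ± 0.461. The adjusted p by camera was 3.48e-16 at the preset correlation, and p = 0.0524 (adjusted p = 0.818) with an estimated correlation. Without replicate 1 of this diet the median was 0.14, and without replicate 2 it was 0.76. Smooth muscle markers were higher in 13 of 15, with a median of 0.31 and an adjusted p of 3.14e-08; MYL9 was 9750 ± 1590 against 6380 ± 1290 and TAGLN 8440 ± 905 against 5730 ± 795. The p with an estimated correlation was 0.00907 (adjusted p = 0.707), and the median was 0.20 without control replicate 1. Macrophage and dendritic cell markers were lower in 11 of 12, with a median of -0.56 and an adjusted p of 6.04e-05. C1QB, a complement component made by macrophages, was 21 ± 8.34 against 45.8 ± 12.3 FPKM. The p with an estimated correlation was 0.108. That list lost its call without replicate 1 of this diet (adjusted p 0.139, median -0.35), while the median was -0.90 without replicate 3 and -0.88 without control replicate 1.

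A further 6 lists passed at 0.5% with smaller or uneven differences, none with an estimated correlation. Adipocyte markers were lower in 10 of 10 (median -0.93, adjusted p 0.0296; p = 0.323 with an estimated correlation), with ADIPOQ, adiponectin, at 16.9 ± 18.1 against 105 ± 117 FPKM. Glycolysis genes were higher in 13 of 18 (median 0.09, adjusted p 0.00639; p = 0.163 with an estimated correlation), with GAPDH at 384 ± 40.7 against 237 ± 40. Skeletal muscle markers were higher in 6 of 9 (median 0.05, adjusted p 0.0056; p = 0.0372 with an estimated correlation), with ACTA1 at 144 ± 17.2 against 95.3 ± 24.9. Oxidative phosphorylation genes were higher in 31 of 55 (median 0.03, adjusted p 0.00294; p = 0.48 with an estimated correlation). With TMM scaling 47 of 55 were higher (median 0.16), and the call ended with the length trend removed (adjusted p 0.0852) and with quantile normalization (0.132), although the medians, 0.05 and 0.07, were no smaller. G1 and G1/S regulators passed as higher (adjusted p 0.0386; p = 0.107 with an estimated correlation) with a median of -0.002 and a mean of 0.04, so the median differed in sign from the test. Ribosomal protein genes also passed as higher (adjusted p 0.0355; p = 0.672 with an estimated correlation) with a median of -0.01 and a mean of -0.03, both opposite in sign to the test, which compares a list with all other genes; with TMM scaling the medians of these 2 lists were 0.11 and 0.11, and their calls ended (adjusted p 0.0682 and 0.173).

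Single libraries ended these 6 calls. Without replicate 2 of the 0.5% diet, glycolysis (adjusted p 0.26), skeletal muscle (0.396) and oxidative phosphorylation (0.152, now lower) lost theirs, and ribosomal protein genes were called lower (0.000263). Without replicate 1 the adipocyte (0.433) and G1 (0.646) calls ended, and without replicate 3 the adipocyte (0.124) and G1 (0.0537) calls. Without control replicate 1 the glycolysis call ended (0.332); without control replicate 2 those of adipocytes (0.0572), G1 (0.156) and oxidative phosphorylation (0.123); and without control replicate 3 those of adipocytes (0.532), oxidative phosphorylation (0.398) and ribosomal proteins (0.342, now lower). Quantile normalization ended the glycolysis call (0.0787, median 0.13), and removing the length trend that of skeletal muscle (0.0594, median 0.13), with medians larger than before. The adipocyte median was -0.48 without control replicate 3 and -1.55 without control replicate 1; in the other fits without a call it stayed between -1.09 and -0.76. With any 1 of the 6 libraries left out, the medians of the other lists ran from -0.05 to 0.19 for glycolysis, -0.15 to 0.20 for skeletal muscle, -0.14 to 0.12 for oxidative phosphorylation, -0.30 to 0.17 for ribosomal proteins and -0.03 to 0.11 for G1 regulators. The highest medians under another scaling were 0.21 for glycolysis (TMM), 0.21 for skeletal muscle (quantile normalization) and 0.14 for G1 regulators (quantile normalization).

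At 1% succinate, RYR2, a calcium release channel, stood at 6.35 ± 1.06 FPKM against 2.81 ± 0.452 in the control (SD, n = 3 in each), and AGAP1, a regulator of membrane traffic, at 7.05 ± 1.9 against 3.08 ± 0.66. MEI1, known from meiosis, was 11.8 ± 7.61 against 2.18 ± 0.545, and CNTNAP2, a neuronal adhesion protein, 2.86 ± 1.39 against 0.537 ± 0.218. HINT1 was 14.3 ± 4.23 against 82.2 ± 12.3, a log2 difference of -2.47 (SE 0.43). LAGE3 was 5.74 ± 1.29 against 11.8 ± 2.33, POP5, a subunit of ribonuclease P, 7.18 ± 0.285 against 12.6 ± 2.22, and ZCCHC10 3.35 ± 1.5 against 7.86 ± 0.859. None of these 8 genes passed the limma test, at an adjusted p of 0.197 each. The 4 genes with higher values are 4365 to 16348 bases long, and HINT1, LAGE3, POP5 and ZCCHC10 are 539 to 2098 bases long, in the direction of the length trend of replicates 2 and 3.

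By limma, 0 genes passed at 1% succinate; 2346 had an unadjusted p under 0.05, 887 higher and 1459 lower, and limma-voom gave 0 with 2231. The groups did not overlap in 2157 genes, 17.8%, where chance gives 10%. Without replicate 1 of this diet, which leaves the 2 libraries that stood apart, 2634 genes passed; without 2% replicate 2, HINT1 alone passed, at an adjusted p of 0.0202. Library weights estimated gene by gene gave 3918 genes, and the default estimate of these weights gave 0. Without the 2 libraries that stood apart, 0 genes passed and 370 had an unadjusted p under 0.05, in a fit that assumes the remaining library to vary like the other groups.

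Genes of ribosomal proteins, which build the ribosome, were lower at 1% succinate in 73 of 73, with a median log2 difference of -0.82 and an adjusted p of 3.47e-19 by camera; the p with an estimated correlation was 0.164 (adjusted p = 0.902). RPS3A was 1670 ± 791 against 3470 ± 582 FPKM and RPL37 743 ± 384 against 1530 ± 294. By limma 0 of these genes passed over all genes tested, and 54 were lower when adjusted over the list alone. Genes of oxidative phosphorylation, the mitochondrial respiratory chain, were lower in 55 of 55, with a median of -0.51 and an adjusted p of 3.96e-13 (p = 0.147 with an estimated correlation); 0 passed over all genes and 27 when adjusted over the list alone. ATP5MF was 39.4 ± 12.4 against 69.1 ± 6.94 FPKM and NDUFB3 26.7 ± 12 against 48.1 ± 8.98. Both lists moved with the 2 libraries that stood apart: ribosomal scores were -0.902 and -0.800 in replicates 2 and 3 and 0.113 in replicate 1, and oxidative phosphorylation scores were -0.521 and -0.690 against -0.014. Without those 2 libraries the medians were -0.17 (adjusted p 0.0892) and -0.14 (adjusted p 0.059). With the length trend removed they were -0.34 (adjusted p 7.42e-12) and -0.08 (adjusted p 0.0544), and then 2 of 73 and 21 of 55 members were higher. With quantile normalization the medians were -0.25 and -0.38, with 4 of 73 and 7 of 55 higher.

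**Figure D2:**
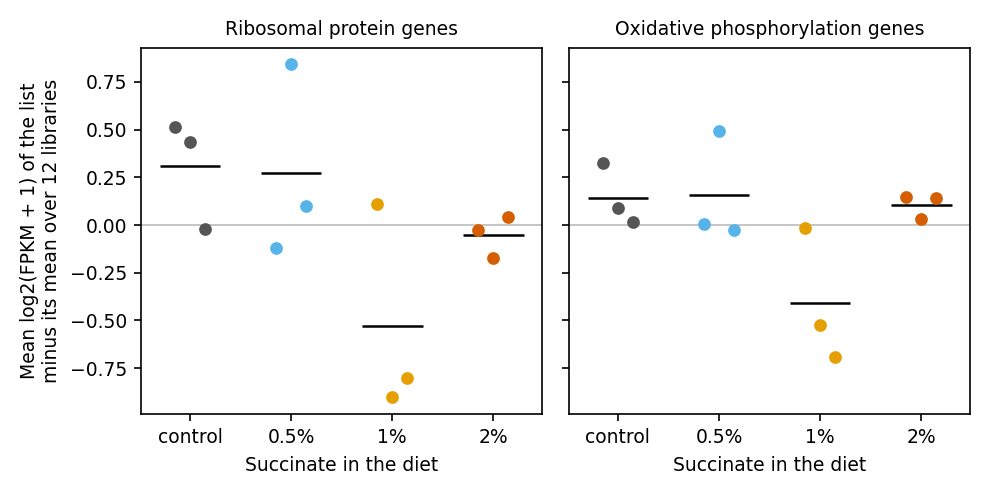
Scores of the ribosomal protein and oxidative phosphorylation lists (mean log2(FPKM + 1) of the members minus its mean over the 12 libraries) by diet; points are libraries and bars are means of 3 libraries. At 1% succinate, replicates 2 and 3 lie at -0.902 and -0.800 for ribosomal proteins and replicate 1 at 0.113.

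S phase and mitosis genes were higher at 1% in 27 of 32, with a median of 0.79 and an adjusted p of 1.38e-07 (p = 0.168 with an estimated correlation). PRC1, which bundles spindle microtubules, was 4.64 ± 3.71 against 0.605 ± 0.415 FPKM, and MKI67, the Ki-67 marker of dividing cells, 1.46 ± 1.37 against 0.0986 ± 0.0536. The median was 0.38 without replicate 2 and 0.30 (adjusted p 0.000963) without both libraries that stood apart. Macrophage markers were lower in 10 of 12, with a median of -0.51 and an adjusted p of 0.0296 (p = 0.298 with an estimated correlation); by limma 0 passed over all genes and 4 when adjusted over the list alone. AIF1, a macrophage calcium-binding protein, was 2.48 ± 0.546 against 5.89 ± 0.493 FPKM. This call ended without replicate 1 of the diet (adjusted p 0.398, median -0.32), without control replicate 3 (0.261, median -0.19) and with the length trend removed (0.312, median -0.09); the median was -1.01 without control replicate 1.

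At 2% succinate, CKAP2, a spindle protein of dividing cells, stood at 13.1 ± 2.05 FPKM against 1.5 ± 0.761 in the control (SD, n = 3 in each), a log2 difference of 2.52 (SE 0.62). NNT, which makes mitochondrial NADPH, was 93.3 ± 11.8 against 58.5 ± 7.23, PGM2, a phosphoglucomutase, 24.8 ± 1.89 against 16.7 ± 0.426, and SRXN1, sulfiredoxin, an antioxidant enzyme, 41.6 ± 3.86 against 27.1 ± 2. CIART, a repressor of the circadian clock, was 10.4 ± 2.1 against 20.8 ± 3.33, AIF1 2.64 ± 0.822 against 5.89 ± 0.493, FRZB, a secreted WNT antagonist, 9.74 ± 1.22 against 20.9 ± 3.06, and AMN1 6.87 ± 0.997 against 12.4 ± 0.735. None of these 8 genes passed the limma test, at an adjusted p of 0.999 each.

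By limma, 0 genes passed at 2% succinate; 383 had an unadjusted p under 0.05, 190 higher and 193 lower, and limma-voom gave 0 with 369. The groups did not overlap in 1715 genes, 14.2%, where chance gives 10%. In a fit of only these 6 libraries 5 genes passed: ANLN, CKAP2, KIF20A and TOP2A, which act in cell division, and LOC101120481, with adjusted p from 0.0299 to 0.0357. LOC101120481 alone passed without 1% replicate 1 (adjusted p 0.00488) and without both 1% libraries that stood apart (0.01). It stood at 5.70 ± 0.622 FPKM against 1.24 ± 0.230. Library weights gave 64 genes by the default estimate and 2 by the gene-by-gene estimate.

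S phase and mitosis genes were higher at 2% succinate in 25 of 32, with a median log2 difference of 1.00 and an adjusted p of 1.19e-19 by camera; the p with an estimated correlation was 0.0347 (adjusted p = 0.818). By limma 0 passed over all genes and 21 when adjusted over the list alone, all higher. TOP2A, which untangles DNA before mitosis, was 4.92 ± 0.591 against 0.767 ± 0.205 FPKM, UBE2C, which marks mitotic proteins for destruction, 6.24 ± 1.63 against 0.784 ± 0.519, and CDK1, the mitotic kinase, 4.28 ± 0.929 against 0.861 ± 0.299. The 7 members with lower values, which were noted after the values were seen and not tested as a group, included the DNA replication helicase genes MCM2 to MCM7, with MCM7 at 28.1 ± 3.17 against 33.3 ± 2.68 and MCM2 at 3.51 ± 0.352 against 3.95 ± 0.698. RRM1, a subunit of the enzyme that makes deoxynucleotides, was 26.1 ± 1.55 against 26.5 ± 1.48. At the lower doses MCM2, MCM3 and MCM4 were not lower, with MCM4 higher by 0.08 at 0.5% and 0.19 at 1%. The list's median stayed between 0.94 and 1.04 with any of the 6 libraries left out. Of its 40 members, 32 were tested. The filter did not use the diets, but a member low in the control could pass it through succinate libraries alone. With a lower filter on FPKM the list was still called by camera at the preset correlation. The median is of log2(FPKM + 1), which shrinks changes of members near or below 1 FPKM.

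Macrophage and dendritic cell markers were lower at 2% in 12 of 12, with a median of -0.65 and an adjusted p of 1.38e-07 (p = 0.0517 with an estimated correlation); by limma 0 passed over all genes and 2, AIF1 and C1QB, when adjusted over the list alone. C1QB was 21.4 ± 3.07 against 45.8 ± 12.3 FPKM. The median was -0.38 without control replicate 2. Ribosomal protein genes were lower in 72 of 73, with a median of -0.35 and an adjusted p of 3.96e-13 (p = 0.247 with an estimated correlation), and 0 passed when adjusted over the list alone; the median was -0.22 with the length trend removed and -0.11 with quantile normalization, with 7 and 13 members higher. Neuron and glia markers were lower in 11 of 11, with a median of -0.40 and an adjusted p of 0.00245 (p = 0.0984 with an estimated correlation); VIP, a neuropeptide of the gut wall, was 2.88 ± 2.62 against 9.23 ± 2.16 FPKM. That call ended without control replicate 2 (adjusted p 0.15, median -0.17), and the median was -0.71 without control replicate 1.

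**Figure D3:**
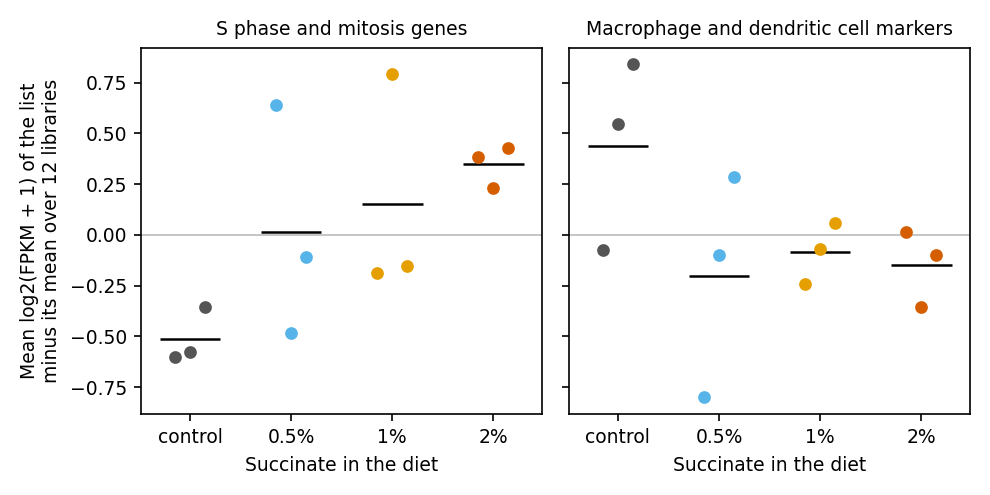
Scores of the S phase and mitosis list and of the macrophage and dendritic cell list (mean log2(FPKM + 1) of the members minus its mean over the 12 libraries) by diet; points are libraries and bars are means of 3 libraries. The S phase score was -0.51 ± 0.14 in the control and 0.35 ± 0.10 at 2% succinate (SD, n = 3), while at 0.5% and 1% a single library in each, at 0.637 and 0.794, lay above the others.

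With fry, 0 lists passed at any dose, and with an estimated correlation the smallest adjusted p over the 78 tests was 0.707.

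Genes of succinate metabolism and others of the fixed set were measured in every diet, and none of those named here passed at any dose. SUCNR1, the succinate receptor, was 0.79 ± 0.293 FPKM in the control and 0.443 ± 0.37, 0.494 ± 0.226 and 0.593 ± 0.237 at 0.5%, 1% and 2% (SD, n = 3 in each), too low to be tested. The succinate dehydrogenase subunit SDHA was 57.6 ± 6.94 in the control and 62.9 ± 8.17, 58 ± 9.08 and 58.1 ± 6.59 with rising dose, and SDHB was 11.6 ± 0.182, 12.7 ± 2.76, 11.4 ± 0.855 and 12.1 ± 1.25. SUCLG1, a subunit of succinyl-CoA ligase, was 134 ± 6.62, 143 ± 32.8, 105 ± 14.1 and 137 ± 8.97. The oxygen-sensitive regulator HIF1A was 15.1 ± 3.77, 12.5 ± 3.42, 12.2 ± 2.07 and 15.6 ± 3.93. Cyclin D1 (CCND1) was 30 ± 4.25, 25.4 ± 12.1, 22.5 ± 4.75 and 22.2 ± 5.13, its partner CDK4 39.4 ± 3.45, 42.1 ± 7.4, 31.9 ± 3.97 and 37.5 ± 4.31, and the replication clamp PCNA 26.9 ± 1.53, 29.5 ± 5.58, 21.1 ± 6.36 and 28.8 ± 5.07. MKI67 was 0.605 ± 0.576 at 0.5% and 0.998 ± 0.249 at 2%. The monocarboxylate carrier SLC16A1 (LOC443456 in the file) was 34.3 ± 13.5, 38.2 ± 18.1, 40.6 ± 8.9 and 39.2 ± 4.41. Smooth muscle actin ACTA2 varied widely, at 239 ± 191, 372 ± 201, 164 ± 178 and 211 ± 259. The sodium-proton exchanger SLC9A3 averaged 0.0638 ± 0.0786 FPKM or less in each diet.

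The other lists did not pass at any dose. Their medians at 0.5%, 1% and 2% were -0.03, -0.20 and 0.05 for succinate and the tricarboxylic acid cycle (smallest adjusted p 0.0988), -0.07, -0.23 and 0.01 for ketogenesis and fatty acid use (0.168), -0.10, -0.05 and 0.05 for cholesterol synthesis (0.44), -0.06, 0.03 and 0.08 for hypoxia-inducible factor targets (0.168), and -0.17, -0.002 and -0.08 for acid, proton and ion transport (0.57). They were -0.03, -0.13 and -0.02 for apoptosis (0.57), -0.06, 0.03 and 0.11 for growth factor signalling (0.536), -0.19, 0.07 and 0.02 for WNT, NOTCH, TGF-beta and Hippo signalling (0.441), -0.32, -0.18 and -0.09 for inflammation (0.441), and -0.20, -0.16 and -0.16 for interferon response (0.127). For immediate early and heat shock genes they were -0.19, -0.27 and 0.06 (0.144), for endoplasmic reticulum stress -0.12, -0.22 and -0.01 (0.168), for the basal epithelial layer -0.07, -0.06 and -0.04 (0.57), for cell junctions -0.03, -0.01 and 0.05 (0.416), for fibroblasts -0.11, 0.26 and -0.02 (0.44) and for endothelium -0.13, -0.09 and -0.03 (0.808). In 19 of the 48 tests of these 16 lists the median differed in sign from the test, and in 14 the mean did; over all 78 list tests these numbers were 24 and 19. At the doses without a call, the medians were -0.02 and 0.12 for G1 regulators at 1% and 2%, 0.01 and 0.05 for glycolysis, 0.11 and 0.12 for smooth muscle, -1.05 and -0.22 for adipocytes and -0.09 and -0.11 for skeletal muscle; they were -0.10 and 0.11 for neurons and glia at 0.5% and 1%, and -0.04 for oxidative phosphorylation at 2%. The lists with fewer than 5 tested members were not tested. Their medians at 0.5%, 1% and 2% were -0.57, 0.06 and 0.06 for 4 suprabasal genes, -0.39, -0.30 and -0.36 for 4 T and natural killer cell markers, -0.48, -0.33 and -0.34 for 3 neutrophil and mast cell markers, 0.14, -0.71 and 0.01 for the B and plasma cell marker JCHAIN, and -0.64, 0.42 and -0.22 for HBB.

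Comparisons between doses ask whether the response depends on the amount of succinate. Ribosomal protein genes were lower at 1% than at 0.5% (median -0.82, adjusted p 2.34e-26; p = 0.108 with an estimated correlation) and lower at 2% than at 0.5% (median -0.33, adjusted p 2.52e-18; p = 0.174 with that correlation). The second difference rests largely on replicate 2 of the 0.5% diet, whose score was 0.841: without it the median was -0.05 (adjusted p 0.00348), and quantile normalization ended the call (0.102, median -0.07). Without that library the first median was -0.53, and without replicate 1 of that diet the second was -0.52. With the length trend removed the medians were -0.30 and -0.19, and with quantile normalization the first was -0.20. Oxidative phosphorylation genes were lower at 1% than at 0.5% (median -0.60, adjusted p 2.16e-20; p = 0.0775 with an estimated correlation) and higher at 2% than at 1% (median 0.50, adjusted p 8.75e-17; p = 0.106); with the length trend removed these medians were -0.16 and 0.18. Without the 2 libraries of the 1% diet that stood apart, oxidative phosphorylation had medians of -0.19 against 0.5% (adjusted p 0.00028) and 0.15 at 2% against 1% (0.147, no call). The ribosomal median at 1% against 0.5% was then -0.15 (adjusted p 0.00304). Smooth muscle markers were lower at 2% than at 0.5% (median -0.28, adjusted p 0.00109, and p = 0.0542 with an estimated correlation). The call was kept with any library of these diets left out, with medians from -0.40 (without 0.5% replicate 3) to -0.16 (without 2% replicate 1). It was also kept with TMM scaling (-0.40, adjusted p 0.0028) and with the length trend removed (-0.30, 0.000145). Quantile normalization ended it (adjusted p 0.995, median 0.06). That scaling forces the most abundant genes to common values, and 13 of these 15 markers were in the top 1%. Of the 78 list tests between doses 6 more passed. They were ribosomal proteins at 2% against 1% (median 0.48, adjusted p 5.69e-09; p = 0.334 with an estimated correlation), the tricarboxylic acid cycle at 2% against 1% (0.20, 0.0403; p = 0.105 with that correlation), and neurons and glia at 2% against 1% (-0.66, 0.0276; p = 0.169 with that correlation) and against 0.5% (-0.21, 0.00272; p = 0.0984 with that correlation). Oxidative phosphorylation (-0.04, 0.00224; p = 0.459 with that correlation) and skeletal muscle (-0.16, 0.00224; p = 0.0247 with that correlation) passed as lower at 2% than at 0.5%. With an estimated correlation the adjusted p of each list named was 0.997.

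Some of these 6 calls changed with a single library or the scaling. Without replicate 2 of the 0.5% diet, oxidative phosphorylation at 2% against 0.5% turned higher (median 0.14, adjusted p 0.367), as it did with the length trend removed (0.04, 0.466), and quantile normalization ended that call (0.432) with the median at -0.05. The skeletal muscle call ended without replicate 2 (median -0.02, adjusted p 0.155) or replicate 1 (-0.13, 0.0759) of the 0.5% diet and with the length trend removed (-0.13, 0.0665). Neurons and glia at 2% against 0.5% lost their call without 0.5% replicate 3 (median -0.05, adjusted p 0.203). At 2% against 1% they lost it without 1% replicate 1 (0.305) or 2 (0.0553), without 2% replicate 2 (0.148) and with quantile normalization (0.102), but the median stayed between -0.69 and -0.63; without both 1% libraries that stood apart it was -0.25 (0.0035). The tricarboxylic acid cycle call ended without 1% replicate 1 (0.253), without 2% replicate 1 (0.0815) or 2 (0.0652), and with each of quantile normalization (0.453), TMM scaling (0.0567) and the length trend removed (0.2). Its median was 0.27, 0.21 and 0.18 without those libraries and 0.20 with TMM scaling, so it hardly shrank there, but 0.07 with quantile normalization and 0.13 with the length trend removed. Without both 1% libraries that stood apart it was 0.14 (0.0612). For ribosomal proteins at 2% against 1% the median was 0.29 without 1% replicate 2, 0.81 without 1% replicate 1, 0.15 with quantile normalization and 0.11 with the length trend removed (adjusted p 0.0333). Without both 1% libraries that stood apart it turned to -0.18 (adjusted p 0.000205). Other moves beyond 1.5 times kept their calls. The oxidative phosphorylation median at 2% against 0.5% ran from -0.16 to -0.02 without any 1 of the other 5 libraries, and was -0.16 with TMM scaling. Skeletal muscle was at -0.38 without 0.5% replicate 3, -0.29 without 2% replicate 2 and -0.33 with quantile normalization. Neurons and glia at 2% against 0.5% were at -0.35 without 0.5% replicate 1 and -0.36 with quantile normalization.

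By limma, 0 genes passed between 1% and 0.5%, where 2440 had an unadjusted p under 0.05; 0 passed between 2% and 1%, with 1227; and 0 passed between 2% and 0.5%, with 783. By limma-voom these were 0 with 2322, 0 with 1120 and 0 with 572. Without 1% replicate 1, which leaves the libraries that stood apart, 2372 genes passed between 1% and 0.5% and 1556 between 2% and 1%. The median log2 difference of all genes between 2% and 0.5% was 0.11, and 0.01 with TMM scaling.

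The linear trend asks which genes follow the dose. Of the 8 genes with the smallest p, CIART was at 20.8 ± 3.33, 16.5 ± 2.89, 11.6 ± 3.33 and 10.4 ± 2.1 FPKM from control to 2% (SD, n = 3 in each). NR1D1, a nuclear receptor that represses clock genes, was at 19.7 ± 10.6, 17.2 ± 5.84, 8.84 ± 4.1 and 5.67 ± 0.675. No list of clock genes was tested. Genes of cell division were CKAP2, with a slope of 1.18 log2 units per percent (SE 0.29), and BIRC5, survivin, at 0.307 ± 0.21 in the control and 1.96 ± 0.718 at 2%. The others were DCTPP1 (12.6 ± 1.66 to 7.87 ± 1.14), NSMCE4A, of a DNA repair complex (20.1 ± 1.58 to 28.8 ± 1.01), NNT (slope 0.34, SE 0.09) and MALT1 (9.71 ± 3.09 to 15.7 ± 1.31). By limma 0 genes passed, at an adjusted p of 1 for each, 388 had an unadjusted p under 0.05, and limma-voom gave 0 with 401.

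The F test asks for any difference among the diets. PGM2 was 12.7 ± 1.35 FPKM at 0.5% and 24.8 ± 1.89 at 2%, RYR2 2.88 ± 0.282 at 0.5% and 6.35 ± 1.06 at 1%, and SOX5, a transcription factor of cartilage and nerve development, 1.69 ± 0.283 at 0.5% and 3.7 ± 0.127 at 1% (SD, n = 3 in each). FAM221B was 4.78 ± 0.852 and 12.8 ± 3.91, FRYL 7.1 ± 1.22 and 16.9 ± 1.52, and DUXB 0.803 ± 0.515 and 3.45 ± 0.196 at 0.5% and 1%. LGALS1 was 439 ± 195 at 0.5% and 135 ± 27.3 at 1%, and ACYP2, an acylphosphatase, 5.1 ± 2.04 at 1% and 13.1 ± 1.59 at 2%. By limma 0 genes passed, with an adjusted p of 0.396 for each of these; 1521 had an unadjusted p under 0.05 and limma-voom gave 0 with 1353. Without 1% replicate 1, 1344 genes passed.

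The doses share the 3 control libraries, which alone makes their differences correlate. Across genes, Pearson's r was 0.41 between 0.5% and 1%, 0.44 between 0.5% and 2%, and 0.57 between 1% and 2%, against means of 0.48, 0.46 and 0.46 over 200 permutations of the libraries that keep a shared control. The covariances were 0.0482, 0.0322 and 0.0617 against 0.0438, 0.0434 and 0.0419, each inside the range of the permutations. No gene was called at more than 1 dose, since 0 were called by limma at each. In 0 of 200 permutations was the S phase list's mean difference at least 0.53, the smallest of its 3 values, at all 3 doses. In 43 it was above 0 at all 3. The permutations shuffled the libraries' deviations from their diet means. List means were counted for this list alone of the 26 tested, and for a rise only. They therefore give no p-value adjusted for that choice.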

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

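The tests that removed the length trend, scaled by TMM or left out 2 libraries were chosen only after the data were seen. No test for outlying samples was run on groups of 3 libraries; replicates 2 and 3 of the 1% diet were noted from their correlations and first component only. Of the 11 list tests past the threshold between doses, 3 were picked out, all of ribosomal proteins or oxidative phosphorylation. In these the list was also called by camera against the control at both doses, in opposite directions. The calls as higher at 0.5% are relative to all other genes. The medians there were -0.01 for ribosomal proteins, with a mean of -0.03, and 0.03 for oxidative phosphorylation. Both calls at 0.5% ended with the length trend removed (adjusted p by camera 0.991 and 0.0852). The change of oxidative phosphorylation genes at 1% differed from that at 0.5% (adjusted p 2.16e-20, median difference -0.60), as did that of ribosomal protein genes (adjusted p 2.34e-26, median difference -0.82). The ribosomal protein genes also differed between 2% and 0.5% (adjusted p 2.52e-18, median difference -0.33), which rests largely on replicate 2 of the 0.5% diet: without it the median difference was -0.05 (adjusted p 0.00348). With an estimated correlation the p values were 0.0775, 0.108 and 0.174, each with an adjusted p of 0.997, so none of the 3 holds there.

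For the ribosomal protein genes at 1%, whose median log2 difference was -0.82, the tables argue against scaling by a few abundant genes, since factors that trim such genes (TMM) left the median at -0.80. Quantile normalization gave -0.25, but it forces the most abundant genes of every library to common values, which limits any change in these genes. The length trend between libraries may account for much of the difference: with it removed the median was -0.34. The difference could also belong to replicates 2 and 3 of the 1% diet, since without them the median was -0.17, and these 2 libraries have the strongest trend towards long genes, though not the only length trend. Whether the diet itself contributed stays open: with 1 library of that diet left, the adjusted p was 0.0892 in a fit that takes its spread from the other diets.

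Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The number of genes at an unadjusted p under 0.05 was 562 at 0.5% (highest other split 1235; 4 of 10 as large, the real one included), 2346 at 1% (3061; 2 of 10) and 383 at 2% (904; 2 of 10). Between doses it was 2440 for 1% against 0.5% (3166; 3 of 10), 1227 for 2% against 1% (2956; 3 of 10) and 783 for 2% against 0.5% (523; 1 of 10). The lists past the threshold numbered 9 at 0.5% (12; 3 of 10), 4 at 1% (10; 6 of 10) and 4 at 2% (9; 7 of 10). For the linear trend, 51 of 100 assignments of the 12 libraries gave at least the real 388 genes, and for any difference among diets 15 of 100 gave at least the real 1521, so chance cannot be excluded for either. The highest other assignments gave 3743 and 3201 genes. The first is several times the real count, which points to a structure of the samples, but no test here says which structure.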

How the results depend on the processing

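The fits by limma-voom, with TMM scaling, with the length trend removed, with library weights (both estimates) and without the 2 libraries that stood apart were chosen after the data were seen. The replicate numbers showed no consistent pairing of the samples. Between diets, deviations from the diet means had a mean r of -0.03 for libraries of equal number and 0.02 for others. For equal numbers r ran from -0.33 to 0.26, and 6 libraries matched best with one of their own number, so a pairing cannot be excluded. With the numbers as a block 0 genes passed by limma in each comparison, with 509, 2240 and 351 at an unadjusted p under 0.05 for the 3 doses. The main counts of genes were 0 in each comparison and those of lists 9, 4 and 4. Of the counts under an alternative, 233 stayed within 1.5 times the main count and 36 did not. Of the values of single genes and lists, 1729 kept their direction and side of the threshold or moved by less than 1 SD, 38 moved by more, 37 came past the threshold, 79 no longer passed and 5 reversed.

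Gene counts away from 0 were these. Without a filter CCDC152 passed between 1% and 0.5% (1 gene), and in the fit of only 6 libraries 5 genes passed at 2%. The default library weights gave 64 genes at 2%, 1 (PGM2) between 2% and 0.5%, and 22 for the trend. This estimate gave a convergence warning and a weight of 0.00118 for 1% replicate 2. The gene-by-gene estimate was added for that reason and gave that library a weight of 3.63. It gave 3918 genes at 1%, 2 at 2% (LOC101119680 and LOC101120481), 1791 between 1% and 0.5%, 3313 between 2% and 1%, 1 (PGM2) between 2% and 0.5% and 3162 for the F test. The 2 estimates disagree on the same library, so neither bears out a call. Without both 1% libraries 1 gene (LOC101120481) passed at 2%, between 2% and 0.5% and in the F test, 2 (with LOC114109518) between 1% and 0.5% and 1 (LOC114109518) between 2% and 1%.

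With each library left out in turn, counts ran from 0 to 2634 at 1%, 0 to 1 at 2%, 0 to 2372 between 1% and 0.5%, 0 to 1556 between 2% and 1%, 0 to 1 between 2% and 0.5%, and 0 to 1344 for the F test, and stayed at 0 for 0.5% and the trend. The highest values came without 1% replicate 1. Replicates 2 and 3, the closest pair within that diet (r 0.9593), then set its mean and spread. Whether this accounts for the counts was not tested. FRZB passed between 2% and 1% without 0.5% replicate 1 and MT-ND1 between 2% and 0.5% without 2% replicate 2.

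The lists past the threshold at 0.5% fell from 9 to 5 with quantile normalization and to 5 with the length trend removed; at 2% they went from 4 to 7 with that trend removed, and from 3 to 8 with a library left out (8 without control replicate 1). With an estimated correlation, and with fry, 0 lists passed at each dose. Ribosomal proteins at 0.5% reversed with quantile normalization (adjusted p 0.0787), with fry (0.98) and without 2 single libraries; their adjusted p ran from 1.95e-10 to 0.342 with a library left out. For oxidative phosphorylation at 0.5% it ran from 3.33e-08 to 0.398, reversed without 0.5% replicate 2. Except where the fewer samples or the forced ranks show it, the cause was not tested.

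The planned edgeR and DESeq2 fits, RLE and upper-quartile factors were not run, since the plan kept count models for a file of counts. Reads were recovered from the FPKM, and TMM and limma-voom used them, so leaving out the other count models was a choice. For glmTreat, limma treat stood in. The list test was not run without a filter. A simulated 2-fold change was called in 36.4% of genes with 3 libraries a diet, so many changes of that size can be missed.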

Other observations

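The tests of all succinate libraries against the control, of smooth muscle as the source, and of the 2% diet alone for a single library were chosen only after the results were seen.

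With the 9 succinate libraries set against the 3 control libraries, LOC101119680 lay at 1.7 to 3.14 FPKM in the control and at 0.0818 to 0.995 with succinate, a log2 difference of -1.40 (SE 0.19) and an adjusted p by limma of 0.091, the smallest of that comparison. HINT1 lay at 70.5 to 95 against 9.55 to 57.9 FPKM, the complement gene C1QB at 37.3 to 59.9 against 11.7 to 28, and AIF1 at 5.53 to 6.45 against 1.71 to 5.21, with no overlap in any of them. These genes were picked from those with the smallest p, which favours such separation. LOC101119680 lay below 1 FPKM in all succinate libraries, so it passed the filter through the 3 control libraries alone. Its separation at 1 FPKM was therefore a condition of its being tested. LOC101120001, also among those with the smallest p, did overlap, at 3.51 to 6.39 against 0.0736 to 5.67. The adjusted p by limma was 0.566 for HINT1 and 0.76 for C1QB and AIF1. By limma 0 genes passed, and 738 had an unadjusted p under 0.05, 192 higher and 546 lower. The macrophage list score differed by -0.58 (exact permutation p = 0.0273, two-sided, adjusted p 0.355 over 26 lists), with 5 of 9 succinate libraries below all controls; it was -0.38 without control replicate 3 and -0.84 without control replicate 1.

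The mitochondrial gene MT-ND1 stood at 185 and 201 FPKM in replicates 1 and 3 of the 2% diet and at 779 to 2940 in the other 10 libraries, and MT-ND5 stood at 37.7 FPKM in replicate 1 of that diet and at 8.04 or less elsewhere. These genes were singled out after their values were seen.

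Genes of S phase and mitosis had a higher score at every dose than in the control, by 0.68 over all succinate libraries, and 8 of the 9 lay above all 3 controls. The tables argue against a length trend as the whole source, since the median at 2% was 1.04 with the trend removed. General leukocyte genes had a median of -0.21 at 2%, with SEs from 0.29 to 0.38 per gene. That met the bound set beforehand against a general rise in blood or infiltrating leukocytes. These genes measure leukocytes as a whole, so the test cannot tell whether the dividing cells were leukocytes. At 2% a single library is also not the source, as the lowest median with a library left out was 0.94; at every dose together this cannot be told apart, since the bound set beforehand, a median above 0, was too loose beside a lowest median of 0.14 at 0.5% and a standard error of 0.37 for a difference between 2 and 3 libraries. Chance spread between libraries cannot be told apart either: 6 of the 220 splits into 3 and 9 gave a difference as large (highest other 0.83; exact permutation p = 0.0273), and the bound of 5% set beforehand ignored that 26 lists were examined, over which the adjusted p was 0.355. In 0 of 200 permutations did the list reach 0.53, its smallest dose difference, at all 3 doses. That count was made for this list alone, so it does not settle the point. At 2%, 25 of 32 tested members were higher. The 7 lower ones were the replication genes MCM2 to MCM7 and RRM1, with log2 differences from -0.25 to -0.02, so these did not share the rise. Members low in the control could also pass the filter through succinate libraries alone. A response of dividing cells to succinate may be a hypothesis for further libraries, with chance left open.

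Epithelial markers were near 0 in all 12 libraries, although the series title concerns rumen epithelial cells. Reads lost between near-identical keratin copies do not explain it, since 16 single-copy epithelial genes had a median of 0.04 FPKM. Libraries made mainly from the smooth muscle wall would be consistent with 15 of 15 smooth muscle markers among the top 5% of genes. The labels name no tissue, no other explanation was tested, and no statement about epithelial cells can be drawn from these values.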
